A study of Arabidopsis thaliana with 16 samples.

How the data were processed

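RNA from Arabidopsis thaliana roots was sequenced in 16 libraries on a BGISEQ-500 instrument. Per the labels, 7 libraries came from a line carrying pE7:shy2-1:GR and 9 from a line carrying pE7:GFP. SHY2 is IAA3, an Aux/IAA protein that represses auxin-responsive transcription, and shy2-1 is a dominant allele of it. GR is the glucocorticoid receptor domain, which holds a fusion protein outside the nucleus until a steroid such as dexamethasone is given. The labels do not spell out pE7, and the line names are kept as given. Seedlings spent 24 h on plates with 0.1 nM dexamethasone, 1 µM dexamethasone or ethanol alone (mock), after which roots were frozen. The age at transfer differs between the series text and the treatment protocol and is not printed here.

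Per the labels, the groups were SHY2-GR mock (3 libraries), SHY2-GR 0.1 nM (2), SHY2-GR 1 µM (2), and GFP mock, GFP 0.1 nM and GFP 1 µM (3 each). Libraries are named below by group and replicate number. The labels name SHY2-GR mock 1 as a control for 0.1 nM, mock 2 as a control for 1 µM and mock 3 as a control for both. Nothing in the labels says whether replicates came from separate plates or sowings, so p-values measure the spread between these libraries, which may be technical. No batch or date is given in the sources used here.

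The deposited files hold, per gene and library, an expected count and an FPKM value. Per the submitters' processing notes, HISAT, StringTie, Cufflinks and DESeq2 were used with the TAIR10 genome; their versions, roles and order are not given in the sources used here. Between 16.66% and 18.51% of the deposited expected counts in a library were not whole, and no entry was 0, so a gene without an entry in a library was taken as 0. Which program wrote the deposited FPKM values, and whether counting used strand, is not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical paralogs, therefore cannot be assigned with certainty. In all, 28861 genes had an entry in at least 1 library, 21237 of them in every library. The reference annotation matched 28829 gene identifiers, and the remaining 32 were gene models made by the submitters' assembly. Gene names and coordinates are those of the reference annotation given for TAIR10 chromosomes.

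Expected counts were rounded to whole numbers. Their total lay between 22722751 and 24100593 per library, with 23986 to 24255 genes listed. At this depth a floor of 3 counts in a library corresponds to 0.14 CPM (counts scaled to a common library total), and folds against groups at 0 were computed against that floor. Such floors cover counting error only. No library pair of a group matched within sampling noise. The chi-square per degree of freedom between replicates was 2.03 to 64.6, and the lowest Pearson correlation of log2 CPM was 0.9613.

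Genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) after TMM normalization and filterByExpr, with robust dispersion shrinkage and 1 mean per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each dose against mock in each line, 1 µM against 0.1 nM in the SHY2-GR line, the difference of each dose's effect between the lines, and SHY2-GR mock against GFP mock. Each SHY2-GR dose was compared with the 2 mock libraries labelled as its controls, and the remaining mock was left out of that fit. All other groups stayed in the fit to estimate the spread. Standard errors of log2 fold changes were derived from the F statistic. Values of single genes are given as CPM, mean ± SD.

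Before the data were examined, 23 gene lists with 319 members were fixed: root hair growth, root hair regulators, hair and non-hair cell fate, Aux/IAA, other auxin-induced genes, auxin response factors (ARF), auxin transport, lateral root, ethylene, cytokinin, mitosis, S phase, endodermis, vasculature, cortex with root cap and stem cell niche, photosynthesis as a marker of shoot tissue, iron deficiency, phosphate starvation, defence, jasmonate and wounding, hypoxia, heat shock and touch. Of these members 10 were left out because their gene code did not carry the listed symbol. Among them were CO2 and PEP, so the list of cortex, root cap and niche held no cortex marker when tested. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 23 lists of a comparison. Camera with an estimated correlation and limma's fry were run beside it. Members were also counted after adjustment over the list alone. After the photosynthesis list had been seen, 10 leaf and stomatal lineage genes (YAB1, YAB2, YAB3, YAB5, SPCH, MUTE, FAMA, EPF1, EPF2 and TMM) were taken as a score of shoot identity, the mean of their log2 CPM less its mean over all 16 libraries.

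The rule for named genes was also fixed beforehand. IAA3 and EXPA7 are given in every comparison. Where genes were called, the rule takes the 5 with the largest rise and the 5 with the largest fall among called genes with a mean CPM of at least 2 and no overlap between the libraries compared. It also takes up to 4 called members per list, and otherwise the member with the smallest p of a list that is discussed. Genes named at 1 µM in the SHY2-GR line are followed through the other comparisons. Other genes are said to be chosen after their values were seen.

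The alternatives were DESeq2 size factors, no filter on low counts, a filter of CPM at least 1 in at least 4 libraries, DESeq2's Wald test (DESeq2 1.42.0), limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes at FPKM 1 or more in at least 2 libraries, an added threshold of 1 on the absolute log2 fold change, only the compared groups in the fit, the replicate number as a block, all 3 SHY2-GR mocks as controls, and leaving out each compared library in turn. Leaving out the GFP libraries numbered 1, the shoot identity score as a covariate, and a fit of the SHY2-GR libraries alone were added after the data had been seen. The labels use the same replicate numbers across groups, except that the SHY2-GR dexamethasone groups have no number 3. Deviations from the group means of the same-numbered libraries of GFP mock and GFP 1 µM correlated across genes at 0.58, 0.17 and 0.34, so these numbers were taken to pair the libraries of that comparison; the hint comes from the data, since no label says what a number stands for.

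The steps were tested on simulated counts with 200 changed genes, 100 at each of 2-fold and 4-fold, among 21334 to 21371 genes. For SHY2-GR 1 µM against mock, edgeR recovered 54% of the 2-fold and 94% of the 4-fold changes and called 10 other genes. The shares were 55% and 95% for SHY2-GR 0.1 nM (12 other genes), 57% and 96% for the doses (9), 69% and 94% for GFP 1 µM (13), 83% and 98% for GFP 0.1 nM (12), 27% and 89% for the difference between lines at 1 µM (4), 27% and 79% at 0.1 nM (6), and 78% and 100% for the mocks (6). DESeq2 called 43 to 56 other genes in the same simulations. Camera recovered a list shifted by 1.5-fold in every comparison and called 0 of the other lists. The changed genes were drawn only from genes above a minimum mean CPM, the simulated genes varied independently and the simulated lists were random. The recovered shares need not hold for genes at lower CPM or where variation is shared across a library. They therefore do not tell how many changes were missed in the real libraries. Nor can the simulation show how often camera calls unshifted lists whose genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.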

Results

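Gene expression was measured in roots of 2 Arabidopsis lines, each given no dexamethasone (mock), 0.1 nM or 1 µM dexamethasone for 24 h. One line carried the dexamethasone-inducible SHY2 fusion (SHY2-GR, 7 libraries) and the other carried GFP in its place (9 libraries), so that a response to dexamethasone itself could be set apart from a response to SHY2. The libraries held 22722751 to 24100593 counts. The first principal component took 48.7% of the variance of log2 CPM and the next 9.25%. Among the 7 SHY2-GR libraries the position along the first component was related to the shoot identity score, the mean log2 CPM of 10 leaf and stomatal lineage genes less its mean over all 16 libraries. Pearson's r was -0.954 (exact permutation p = 0.00198 over 5040 orders, n = 7) and Spearman's rho -0.964 (exact permutation p = 0.00278), and this was the single relation tested. Without the 2 libraries farthest from the median score, r was -0.865. The permutations ignored the treatment groups, and the score was chosen after the photosynthesis list had been seen. These p-values therefore do not part shoot content from treatment. The GFP libraries fell into separate clusters on this score, and no coefficient is given for them. YAB1, a gene of leaf polarity, was at 5 to 26.56 CPM in the SHY2-GR libraries. It was at 4.51 to 6.22 CPM in the GFP libraries numbered 1, at 2.12 CPM in GFP mock 2 and at 0.08 to 0.38 CPM in the other GFP libraries.

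SHY2 itself (IAA3, AT1G04240, chromosome 1, 1128149 to 1129689) was at 22.6 ± 4.4 CPM at 1 µM (SD, n = 2) against 16.4 ± 0.41 CPM in its mocks (n = 2), a log2 fold change of 0.47 ± 0.16 (SE). At 0.1 nM it was at 23.5 ± 3.1 CPM (n = 2) against 16.2 ± 0.73 CPM (n = 2), a log2 fold change of 0.53 ± 0.16. Neither passed the test over all genes (adjusted p = 1 and 0.134). The GFP line had 15.6 ± 1.9 CPM of IAA3 in mock, 15.2 ± 0.69 CPM at 0.1 nM and 16.6 ± 1.3 CPM at 1 µM (n = 3 each). In mock the lines differed by 0.05 ± 0.13 (log2, SHY2-GR minus GFP). Counts for IAA3 cannot separate the endogenous gene from the fusion. EXPA7 (AT1G12560, chromosome 1, 4276505 to 4277969), an expansin of root hair cells, was at 56.8 ± 29.0 CPM at 1 µM against 69.5 ± 11.0 CPM in mock, and its 1 µM libraries were at 36.11 and 77.52 CPM. Its log2 fold change was -0.28 ± 0.26 at 1 µM and 0.15 ± 0.25 at 0.1 nM in the SHY2-GR line, and 0.07 ± 0.20 and 0.03 ± 0.20 in the GFP line. Without 1 µM library 1 the value at 1 µM was 0.18, and without library 2 it was -0.96, each with 1 library left at 1 µM. In mock, EXPA7 was at 67.0 ± 8.8 CPM in the SHY2-GR line and 98.1 ± 9.4 CPM in the GFP line (n = 3 each; log2 difference -0.55 ± 0.20, adjusted p = 0.25).

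**Figure D1:**
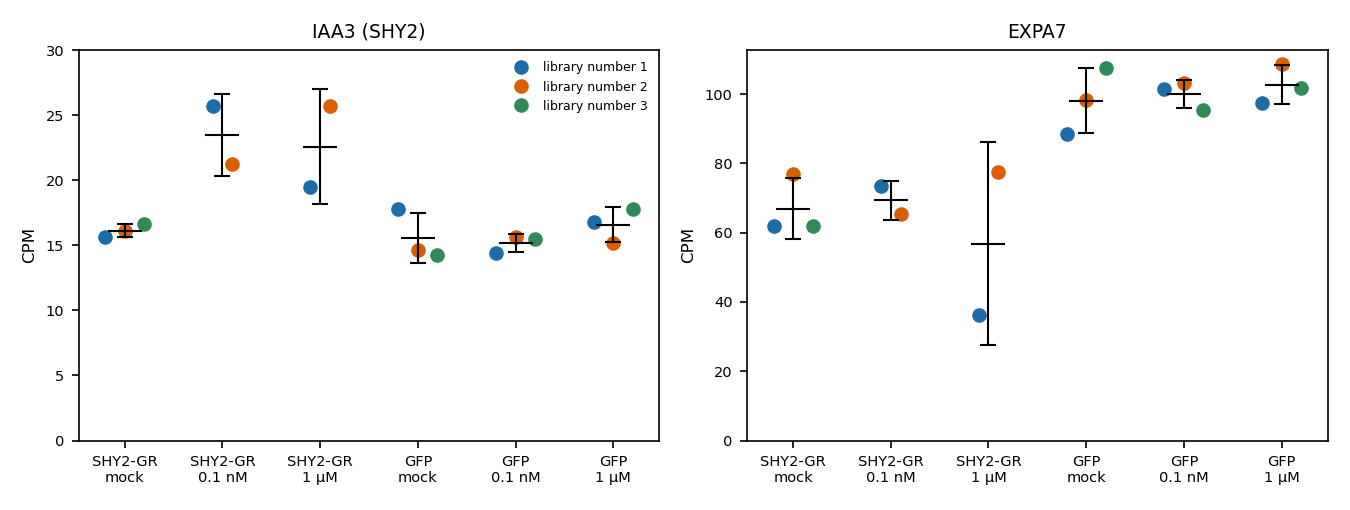
CPM of IAA3 (SHY2) and EXPA7 per library (points, coloured by library number) with the group mean (horizontal line) and SD (whiskers) for mock, 0.1 nM and 1 µM dexamethasone in the SHY2-GR and GFP lines. IAA3 means are 23.5 and 22.6 CPM at 0.1 nM and 1 µM in the SHY2-GR line and 15.2 and 16.6 CPM in the GFP line.

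At 1 µM dexamethasone in the SHY2-GR line, genes of root hair growth were lower than in mock as a group. Of the 47 measured members, which act in wall loosening, tip growth and wall deposition of the hair, 46 had a negative fold change, and the median log2 fold change was -0.39, or 0.763-fold. The list fell by camera (adjusted p = 5.67e-21, and adjusted p = 0.708 with an estimated correlation). XTH26 (AT4G28850, chromosome 4, 14244290 to 14246037), a xyloglucan-modifying enzyme of root hairs, was at 1.29 ± 1.1 CPM against 10.1 ± 2.7 CPM (n = 2 each), a log2 fold change of -2.95 ± 0.56 with an adjusted p of 0.723 over all genes. The extensin EXT6 had a log2 fold change of -1.26 ± 0.29, the root hair specific genes RHS15 and RHS19 -1.48 ± 0.34 and -1.12 ± 0.27, and XTH12 -1.62 ± 0.38. EXT6 with EXT10, and XTH12 with XTH13, are near-identical copies whose reads may be shared. Adjusted over the list alone 6 members were lower and none higher, against 0 adjusted over all genes, and 16 were lower at an unadjusted p under 0.05. The fall rested on 1 µM library 1: the list's mean log2 CPM, centred over all libraries, was -1.278 in that library and -0.258 in library 2, against -0.431, 0.008 and -0.231 in mocks 1, 2 and 3. Without library 1 the adjusted p of the list was 0.27. Without library 2, which left 1 library at 1 µM, the log2 fold change of XTH26 was -4.34.

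**Figure D2:**
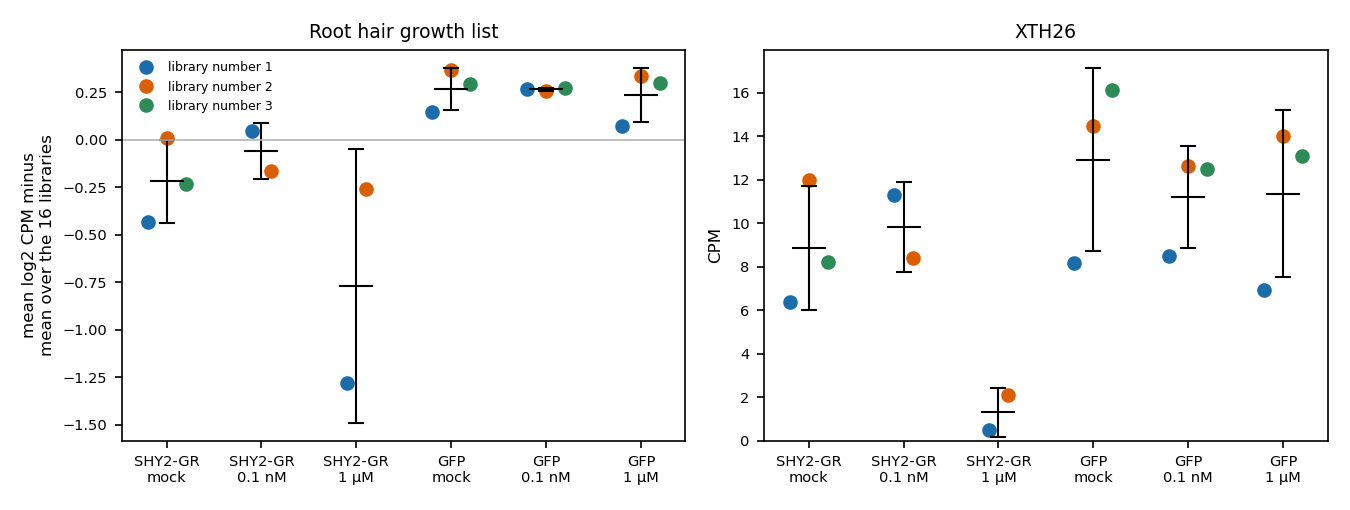
Mean centred log2 CPM of the 47 root hair growth genes and CPM of XTH26 per library (points, coloured by library number), with group mean (horizontal line) and SD (whiskers), for each treatment of both lines. SHY2-GR 1 µM library 1 lies lowest in both panels, at -1.278 and 0.5 CPM.

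The other lists did not pass the test at 1 µM. Regulators of root hair initiation and growth had a median log2 fold change of 0.05 (adjusted p = 0.995; RSL4 -0.42 ± 0.22), and hair and non-hair cell fate genes -0.13 (adjusted p = 0.0595; TRY, a MYB protein of hair patterning, -1.0 ± 0.42). Among auxin lists, Aux/IAA repressors stood at 0.02 (adjusted p = 0.995), other auxin-induced genes at 0.12 (0.961), ARF transcription factors at 0.06 (0.313; ARF7 0.24 ± 0.10), auxin transport at -0.09 (0.239) and lateral root genes at 0.01 (0.995; EXPA17 -0.41 ± 0.14). IAA6, an Aux/IAA gene, was at 1.69 ± 0.79 against 0.4 ± 0.11 CPM (log2 fold change 2.07 ± 0.52), and PID, a kinase that directs PIN auxin carriers, at 5.88 ± 0.48 against 9.76 ± 2.3 CPM (-0.73 ± 0.19). Adjusted over the list alone IAA6 was higher in its list, while PID and 2 further auxin-induced genes were lower in theirs. Adjusted over all genes none passed (IAA6 adjusted p = 0.837, PID adjusted p = 0.964). Median log2 fold changes of the remaining lists were 0.24 for cytokinin (adjusted p = 0.131; ARR6, a type-A response regulator, 0.34 ± 0.12), -0.07 for ethylene (0.131; ERS1 -0.25 ± 0.10), 0.06 for mitosis (0.749), -0.01 for S phase (0.995), -0.01 for endodermis (0.995), 0.10 for vasculature (0.597) and -0.15 for cortex, root cap and niche (0.225; PLT1 -0.39 ± 0.16). They were 0.19 for photosynthesis (0.75; LHCB3 0.31 ± 0.44), -0.06 for iron deficiency (0.131; BHLH39 -0.86 ± 0.28), 0.17 for phosphate starvation (0.178; SQD2 0.31 ± 0.13), -0.77 for defence (0.201), 0.02 for jasmonate and wounding (0.995; JAZ1 -0.74 ± 0.32), -0.17 for hypoxia (0.6), 0.32 for heat shock (0.178) and -0.11 for touch (0.995). Median and mean differed in sign for S phase, endodermis and jasmonate, and for the lateral root list both were above 0 while camera gave the lower direction.

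No single gene was called at 1 µM among 21532 tested by edgeR's quasi-likelihood test, whose lowest adjusted p was 0.153. At an unadjusted p under 0.05 there were 858 genes, 406 higher and 452 lower, where chance gives 1077. DESeq2's Wald test called 24 (8 higher, 16 lower), and limma on FPKM called 0. The gene with the lowest adjusted p, chosen after its values were seen, was the cupin gene AT5G38940, at 4.55 ± 2.1 against 17.7 ± 4.8 CPM (log2 fold change -1.95 ± 0.26). Leaving out either 1 µM library leaves 1 library in that group, which is then assumed to vary like the other groups. Without 1 µM library 1, edgeR called 6 genes, all higher. Without library 2 it called 134, 13 higher and 121 lower. List calls numbered 1 with the labelled controls, 3 without library 1 (root hair growth not among them), 6 without library 2 and 5 without mock 2.

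At 0.1 nM in the SHY2-GR line, the lists of the photosynthetic apparatus and of cytokinin signalling were higher than in mock by camera. Those of root cap, cell division and cell fate were lower. None of these lists was called with an estimated correlation. All 13 photosynthesis genes had a positive fold change, with a median log2 fold change of 1.2 (2.3-fold). LHCA3, a light-harvesting protein of photosystem I, was at 331 ± 65 against 157 ± 27 CPM (n = 2 each; 1.06 ± 0.27), and LHCA1 had a log2 fold change of 1.28 ± 0.35. Of the 15 cytokinin genes 14 were on the higher side, with a median of 0.50 (1.41-fold). The type-A response regulators ARR6, ARR7 and ARR15 had log2 fold changes of 0.49 ± 0.11, 0.90 ± 0.31 and 1.61 ± 0.49, and the cytokinin oxidase CKX5 0.58 ± 0.20. Both lists rose (adjusted p = 1.46e-05 each) and were not called with an estimated correlation (adjusted p = 0.519 for photosynthesis and adjusted p = 0.117 for cytokinin), and 7 and 6 members were higher adjusted over the list alone against 0 each adjusted over all genes. The leaf and stomatal lineage genes were higher in the same libraries, where their score was 2.41 and 2.02 against 0.64 and 1.08 in mocks 1 and 3. The 1 µM libraries 1 and 2 had scores of 2.15 and 1.25, and mock 2, the remaining mock, 1.94. RBCS1A and LHCB1.3, among the most abundant transcripts of leaves, were at 3560 ± 660 and 3030 ± 440 CPM at 0.1 nM, and LHCB1 and RBCS copies share reads.

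Lower at 0.1 nM were the lists of cortex, root cap and niche (7 genes, median log2 fold change -0.64, adjusted p = 0.00512, and adjusted p = 0.117 with an estimated correlation), mitosis (13 genes, median -0.25, adjusted p = 0.00206, and adjusted p = 0.457 with an estimated correlation) and hair and non-hair fate (10 genes, median -0.43, adjusted p = 0.0188, and adjusted p = 0.117 with an estimated correlation). In the first, SMB, a NAC factor of root cap maturation, was at 7.14 ± 0.92 against 13.1 ± 2.4 CPM (-0.89 ± 0.17), and PLT1 and PLT2, which maintain the stem cell niche, had log2 fold changes of -0.69 ± 0.14 and -0.64 ± 0.13. The niche gene WOX5 went the other way (0.60 ± 0.26). So did JKD, at 77.3 and 86.76 CPM at 0.1 nM against 67.95 and 70.13 CPM in mocks 1 and 3. As CO2 and PEP had been left out, this list held no cortex marker. Adjusted over the list alone 5 members were lower and 1 higher. All 13 mitosis genes had a negative fold change (CDKB1;1 -0.36 ± 0.13), none past the test adjusted over the list alone. GL2 and WER, which specify non-hair cells, had log2 fold changes of -0.59 ± 0.15 and -0.56 ± 0.19, and 2 members were lower adjusted over the list alone. Root hair growth genes rose by a median of 0.22 (adjusted p = 0.04, and adjusted p = 0.866 with an estimated correlation), with 37 of 47 on the higher side, 0 called adjusted over the list alone, EXT6 at 0.80 ± 0.27 and XTH26 at 0.42 ± 0.48. Their call ended without mock 1 (adjusted p = 0.331) and without 0.1 nM library 1 (0.391), and that of the fate list without 0.1 nM library 1 (0.0716). With all 3 mocks as controls the root hair, fate and cortex lists were not called (adjusted p = 0.376, 0.0672 and 0.109).

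Of 21516 genes tested at 0.1 nM, 37 were called, 28 higher and 9 lower, each at an adjusted p of 0.049. Among called genes with a mean of at least 2 CPM over the libraries compared and no overlap between groups, the largest rises were in ATSDI1, a marker of sulfur deficiency (AT5G48850, chromosome 5, 19805437 to 19807853), at 4.83 ± 1.8 against 0.983 ± 0.32 CPM (log2 fold change 2.28 ± 0.39, n = 2 each), and AT4G28740, at 7.23 ± 0.86 against 2.19 ± 0.17 CPM (1.70 ± 0.25). Next came the serine carboxypeptidase-like gene SCPL7 (1.36 ± 0.23), the cytochrome P450 gene CYP94D2 (1.33 ± 0.22) and AT1G02475 (1.21 ± 0.21). Under the same limits the largest falls were in AT2G17070 (-1.35 ± 0.22), AT5G40320 (-1.31 ± 0.20), AT3G62570 (-1.06 ± 0.17), the AP2/ERF transcription factor gene AT1G36060 (-1.03 ± 0.15, 53.3 ± 9.5 against 107 ± 13 CPM) and EXPA17. EXPA17 (AT4G01630, chromosome 4, 700566 to 701769), an expansin of lateral root emergence, was at 30.3 ± 2.8 against 52.3 ± 5.6 CPM (-0.80 ± 0.13) and was the only called gene that any list held. The lateral root list as a whole had a median of 0.24 and was not called. PID fell short of the test (-0.93 ± 0.16, adjusted p = 0.0508), as did IAA6 (1.17 ± 0.53). The calls depended on single libraries. Without mock 1 or without 0.1 nM library 1 there were 0, with 0.1 nM library 2 left out 1, and without mock 3 there were 20, of which 5 were among the 37, CYP94D2 and AT1G36060 being the named ones. In mock 2, which was left out of this comparison, CYP94D2 was at 10.02 CPM, against 9.97 and 9.27 CPM in the 0.1 nM libraries. AT1G36060 was at 55.83 CPM in mock 2, against 46.55 and 59.97 CPM at 0.1 nM. For these genes the lack of overlap thus held against the labelled mocks only. With all 3 mocks as controls 0 genes were called, DESeq2 called 990 (790 higher, 200 lower), and DESeq2 size factors in edgeR called 80 (69 higher, 11 lower). At an unadjusted p under 0.05 there were 3790 genes where chance gives 1076.

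**Figure D3:**
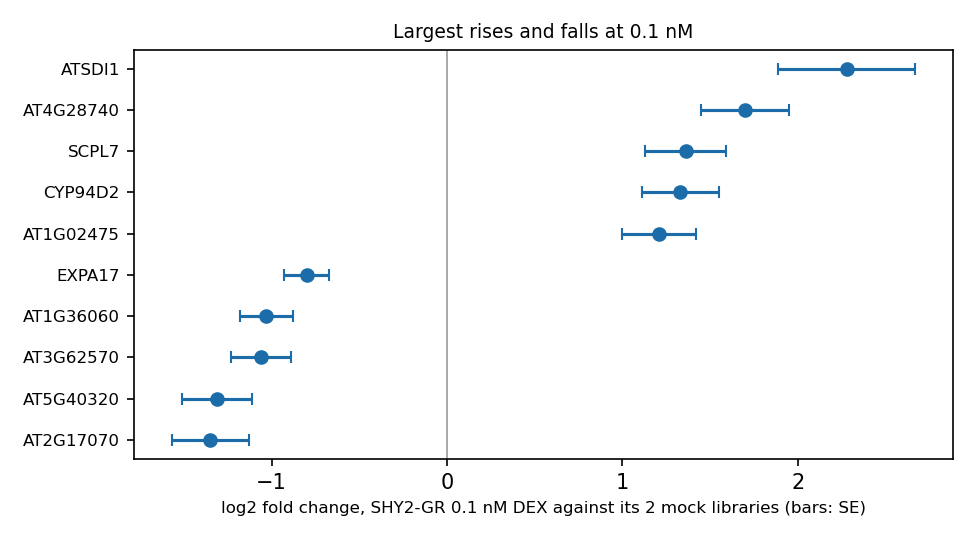
Log2 fold change with its SE (whiskers) of the 10 genes with the largest rise and fall at 0.1 nM dexamethasone against the labelled mocks of the SHY2-GR line, among called genes with a mean of at least 2 CPM and no overlap between groups. Values run from -1.35 for AT2G17070 to 2.28 for ATSDI1.

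**Figure D4:**
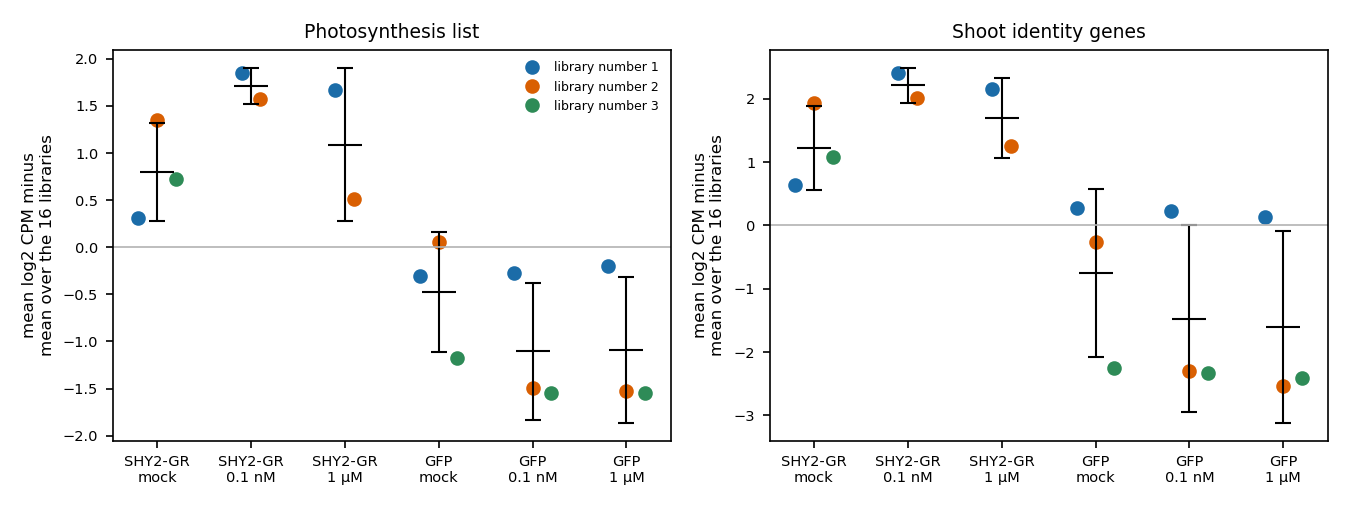
Mean log2 CPM of the 13 photosynthesis genes and of the 10 leaf and stomatal lineage genes, each centred over all 16 libraries, per library (points, coloured by library number) with group mean (horizontal line) and SD (whiskers). The shoot identity score spans 0.64 to 2.41 in the SHY2-GR libraries and -2.54 to 0.273 in the GFP libraries.

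Between the doses, root hair growth genes were lower at 1 µM than at 0.1 nM in the SHY2-GR line. Of 47 members 43 had a negative fold change, the median was -0.41, and the list differed by camera (adjusted p = 7.86e-21, and adjusted p = 0.635 with an estimated correlation). Adjusted over the list alone 9 were lower, and 0 adjusted over all genes. XTH26 was at 1.29 CPM against 9.84 CPM (log2 fold change -2.92 ± 0.56, n = 2 each), EXT6 had -1.42 ± 0.35 and RHS15 -1.62 ± 0.41. Also lower at 1 µM were photosynthesis genes (median -0.54, 13 of 13 negative, adjusted p = 0.00161, and adjusted p = 0.844 with an estimated correlation; LHCA1 -0.77 ± 0.36), cytokinin genes (median -0.20, adjusted p = 0.00138, and adjusted p = 0.565 with an estimated correlation; ARR16 -0.97 ± 0.32) and iron deficiency genes (median -0.41, adjusted p = 0.00139, and adjusted p = 0.635 with an estimated correlation; BTS, a regulator of iron responses, -0.41 ± 0.13). Mitosis genes (median 0.17, adjusted p = 0.00139, and adjusted p = 0.635 with an estimated correlation; CDKB1;1 0.29 ± 0.13) and phosphate starvation genes (median 0.26, adjusted p = 0.00894, and adjusted p = 0.635 with an estimated correlation; MGD2, a galactolipid synthase, 0.71 ± 0.21) were higher. The shoot identity score was 2.15 and 1.25 at 1 µM and 2.41 and 2.02 at 0.1 nM. IAA3 (-0.06 ± 0.15), EXPA7 (-0.29 ± 0.25), PID (-0.11 ± 0.21) and IAA6 (0.94 ± 0.47) did not pass the test. No gene was called among 21552 by edgeR's quasi-likelihood test (899 at an unadjusted p under 0.05, where chance gives 1078, 14 by DESeq2 and 0 by limma on FPKM). SUC1, a sucrose carrier chosen after its values were seen, had the lowest adjusted p, 0.145, at 64.4 ± 1.0 against 101 ± 2.0 CPM. Without 1 µM library 1, the root hair, cytokinin, iron, mitosis and phosphate lists were not called (adjusted p = 0.484, 0.484, 0.89, 0.829 and 0.134), and of the 2 lists called 1 was among the 6. Without 1 µM library 2, which left 1 library at 1 µM, the photosynthesis and phosphate lists were not called. EXPA7 then had a log2 fold change of -0.94 (0.16 without library 1) and XTH26 one of -4.29. Without 0.1 nM library 1 the mitosis list was lost (0.0957), and without library 2 the phosphate list (0.0751), with 1 gene called.

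In the GFP line, dexamethasone was followed by lower photosynthesis genes and higher touch-induced genes at both doses, measured against the same 3 mocks, so part of the likeness between doses may come from those mocks. At 1 µM the 13 photosynthesis genes were all on the lower side with a median log2 fold change of -0.52 (camera adjusted p = 3.08e-06, and adjusted p = 0.666 with an estimated correlation), LHCB2.1 having -0.91 ± 0.42. At 0.1 nM the median was -0.51 (adjusted p = 1.19e-06, and adjusted p = 0.541 with an estimated correlation; 13 of 13 lower; LHCA1 -0.67 ± 0.29). The shoot identity score was 0.273, -0.269 and -2.246 in mocks 1, 2 and 3, and in the dexamethasone groups only the libraries numbered 1 were above -2. Touch genes had a median of 0.46 at 1 µM (3 genes, adjusted p = 3.08e-06, and adjusted p = 0.131 with an estimated correlation) and 0.41 at 0.1 nM (adjusted p = 0.000203, and adjusted p = 0.23 with an estimated correlation). TCH4, a xyloglucan-modifying enzyme, was at 14.3 ± 0.99 against 9.87 ± 1.3 CPM at 1 µM (0.54 ± 0.19, n = 3 each) and was called adjusted over the list alone. The calmodulin-like gene TCH3 had log2 fold changes of 0.37 ± 0.16 at 1 µM and 0.35 ± 0.16 at 0.1 nM. Without GFP mock 2 the photosynthesis list was not called at either dose (adjusted p = 0.0587 at 1 µM and 0.0573 at 0.1 nM), nor was the touch list at 0.1 nM (0.117). Root hair growth genes had medians of -0.02 at 1 µM (adjusted p = 0.556) and 0.00 at 0.1 nM (0.643), with XTH26 at -0.19 ± 0.39 and -0.21 ± 0.39, IAA6 at 0.61 ± 0.40 and 0.00 ± 0.41, and PID at 0.14 ± 0.17 and -0.09 ± 0.17, in the same order.

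Further lists passed the camera test in the GFP line, each lost with an estimated correlation. At 1 µM, mitosis genes had a median log2 fold change of 0.07 (adjusted p = 0.00785, and adjusted p = 0.666 with an estimated correlation), CYCB1;4 having 0.16 ± 0.08. Defence genes stood at 0.49 (adjusted p = 0.0416, and adjusted p = 0.666 with an estimated correlation), with WRKY40, a stress-induced transcription factor, at 1.29 ± 0.60. Endodermis genes stood at 0.13 (adjusted p = 0.0294, and adjusted p = 0.666 with an estimated correlation; CASP4 0.18 ± 0.12). Iron deficiency genes stood at 0.14 (adjusted p = 0.0294, and adjusted p = 0.768 with an estimated correlation; CYP82C4 1.01 ± 0.57). Jasmonate genes stood at 0.14 (adjusted p = 0.0294, and adjusted p = 0.193 with an estimated correlation), with JAZ5, a jasmonate repressor, at 0.75 ± 0.44 (0.09 to 0.29 CPM in mock and 0.35 to 0.41 CPM at 1 µM, close to the floor of 0.14 CPM). Without GFP mock 2 none of these 5 was called (adjusted p = 0.302 for mitosis, 0.382 for defence and for endodermis, 0.0838 for iron and 0.561 for jasmonate), and of the 2 lists called 1 was among the 7. Without mock 3 the endodermis, iron and jasmonate lists were lost (adjusted p = 0.095, 0.0649 and 0.136), which left 4, and without mock 1 the defence and iron lists (adjusted p = 0.112 and 0.221). Leaving out 1 µM library 1 ended the endodermis and jasmonate calls (adjusted p = 0.18 and 0.419), library 2 those of defence, endodermis and iron (adjusted p = 0.451, 0.0656 and 0.269) and library 3 those of defence and iron (adjusted p = 0.131 and 0.107). With the replicate number as a block the defence list was not called either (adjusted p = 0.0607).

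At 0.1 nM in the GFP line the further lists called were cytokinin, defence, endodermis and jasmonate. Cytokinin genes had a median log2 fold change of 0.14 (adjusted p = 0.00531, and adjusted p = 0.264 with an estimated correlation; ARR5 0.26 ± 0.16). Defence genes stood at 0.53 (adjusted p = 0.0043, and adjusted p = 0.23 with an estimated correlation; WRKY40 1.37 ± 0.60). Endodermis genes stood at 0.14 (adjusted p = 0.0464, and adjusted p = 0.651 with an estimated correlation), and jasmonate genes at 0.03 (adjusted p = 0.0345, and adjusted p = 0.23 with an estimated correlation; JAZ5 1.08 ± 0.43, at 0.09 to 0.29 CPM in mock and 0.42 to 0.5 CPM at 0.1 nM). Without GFP mock 2 these 4 were lost (adjusted p = 0.173, 0.117, 0.375 and 0.475 in that order), and 0 lists were called. Without mock 3 the cytokinin, endodermis and jasmonate lists were lost (adjusted p = 0.0725, 0.0759 and 0.105), which left 3, and without mock 1 the endodermis list (adjusted p = 0.0617). Leaving out 0.1 nM library 1 ended the calls of cytokinin, endodermis and jasmonate (adjusted p = 0.127, 0.131 and 0.247), and library 2 those of defence and endodermis (adjusted p = 0.0699 and 0.25).

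At 1 µM in the GFP line no gene was called among 21552 by edgeR's quasi-likelihood test (271 at an unadjusted p under 0.05, where chance gives 1078, 1 by DESeq2 and 0 by limma on FPKM). Chosen after its values were seen, the long non-coding RNA AT4G36032 (chromosome 4, 17044958 to 17047346) was at 14.6 ± 7.4 against 1.31 ± 0.43 CPM (log2 fold change 3.48 ± 0.52, adjusted p = 0.321, n = 3 each). With the replicate number as a block it was the 1 gene called (3.41 ± 0.30, adjusted p = 0.0129), as 1 gene was without 1 µM library 2. It overlaps ARO3, an armadillo repeat gene, so its reads cannot be assigned with certainty. At 0.1 nM it was at 11.1 ± 2.5 CPM (3.08 ± 0.51, adjusted p = 0.508). In the SHY2-GR line it was at 6.72, 4.41 and 13.77 CPM in mocks 1, 2 and 3, above the GFP mocks without any dexamethasone. Its log2 fold change there was -1.74 ± 0.53 at 0.1 nM and 0.65 ± 0.56 at 1 µM. At 0.1 nM in the GFP line 1 gene was called (256 at an unadjusted p under 0.05), which lies outside the rule for named genes. This was AT5G18475, a pentatricopeptide repeat gene (chromosome 5, 6129237 to 6131120), with 0 counts in each of the 3 libraries against 3.04 ± 0.74 CPM in mock, at least 21-fold lower (floor of 3 counts per library, 0.14 CPM; adjusted p = 0.00495). The other libraries of both lines had 1.49 to 4.12 CPM of it. The gene overlaps its neighbour AT5G18470 at one end, and it was not called with only the compared groups in the fit (adjusted p = 0.264). With the replicate number as a block AT5G18475 was not called at 0.1 nM either, and AT4G36032 was called in its place (log2 fold change 3.14 ± 0.30, adjusted p = 0.0277).

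The direct test of the difference between lines asked whether the dexamethasone response of the SHY2-GR line was that of the GFP line. At 1 µM the root hair growth list differed, with a median difference of -0.36 (SHY2-GR minus GFP, log2) and 46 of 47 members negative (camera adjusted p = 3.55e-15, and adjusted p = 0.552 with an estimated correlation). XTH26 had -2.76 ± 0.68. Without SHY2-GR 1 µM library 1 the adjusted p was 0.625. Iron deficiency genes differed by -0.31 (adjusted p = 0.00814, and adjusted p = 0.644 with an estimated correlation; BHLH39 -1.06 ± 0.36), with an adjusted p of 0.989 without that library. By camera, photosynthesis genes (0.58, adjusted p = 0.00814), hair and non-hair fate genes (-0.18, adjusted p = 0.0188), touch genes (-0.60, adjusted p = 0.0343) and defence genes (-0.52, adjusted p = 0.0418) differed as well. With an estimated correlation the adjusted p was 0.672 for photosynthesis and 0.552 for each of the other 3, and each call was lost on leaving out single libraries. At 0.1 nM the photosynthesis list differed by 1.71, with 13 of 13 members positive and 9 higher adjusted over the list alone against 0 adjusted over all genes (adjusted p = 4.61e-08, and adjusted p = 0.466 with an estimated correlation; LHCA1 1.96 ± 0.45). Cytokinin genes differed by 0.39 (adjusted p = 0.00801, and adjusted p = 0.466 with an estimated correlation; ARR6 0.39 ± 0.14). Lower in the SHY2-GR response were the cortex, root cap and niche list (-0.69, adjusted p = 0.01, and adjusted p = 0.256 with an estimated correlation; SMB -0.95 ± 0.22), mitosis (-0.32, adjusted p = 0.00129, and adjusted p = 0.466 with an estimated correlation; CYCB1;4 -0.35 ± 0.12) and hair and non-hair fate (-0.43, adjusted p = 0.01, and adjusted p = 0.231 with an estimated correlation; WER -0.79 ± 0.24). Beside these lists, the shoot identity score was higher at 0.1 nM than in the labelled mocks of the SHY2-GR line. With all 3 mocks the cortex list was not called (adjusted p = 0.18). IAA3 differed by 0.38 ± 0.21 at 1 µM and 0.56 ± 0.21 at 0.1 nM (adjusted p = 0.281 at 0.1 nM), EXPA7 by -0.35 ± 0.33 and 0.12 ± 0.32, and EXPA17 by -0.82 ± 0.17 at 0.1 nM.

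No gene was called in either difference by edgeR's quasi-likelihood test. At 1 µM 586 of 21532 genes had an unadjusted p under 0.05 (lowest adjusted p = 1), and at 0.1 nM 2771 of 21516 (lowest 0.0947, for AT4G36032 and AT5G18475). DESeq2 called 6 at 1 µM and 505 at 0.1 nM, and limma on FPKM called 0 in both. At 1 µM, 1 gene was called without SHY2-GR 1 µM library 1 and 7 without library 2. At 0.1 nM, 18 were called without SHY2-GR mock 3, and 1 and 2 without 0.1 nM libraries 1 and 2. List calls at 1 µM numbered 6, against 2 without SHY2-GR mock 3 and 3 without GFP mock 2, all among the 6. Without SHY2-GR 1 µM library 1 there were 2, of which 0 were among the 6. List calls at 0.1 nM numbered 5, against 8 without SHY2-GR mock 3.

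Without dexamethasone the SHY2-GR line had lower root hair growth genes and higher photosynthesis genes than the GFP line. A leak of the fusion, other differences between the lines, a batch and a different share of shoot tissue cannot be told apart by this comparison. Of the 47 root hair growth genes 45 had a negative fold change, with a median of -0.50 (0.71-fold; camera adjusted p = 2.59e-13, and adjusted p = 0.345 with an estimated correlation). RHS9 had a log2 fold change of -0.63 ± 0.19, and 0 members were called adjusted over the list alone. All 7 regulators of root hairs were lower (median -0.29, adjusted p = 0.00111, and adjusted p = 0.0895 with an estimated correlation), with RSL2, a bHLH factor of hair growth, at -0.70 ± 0.17. Cytokinin genes were lower (median -0.40, adjusted p = 0.000106, and adjusted p = 0.157 with an estimated correlation; ARR6 -0.60 ± 0.09), as were endodermis genes (median -0.42, adjusted p = 0.000459, and adjusted p = 0.304 with an estimated correlation), with ESB1, needed for the Casparian strip, at -0.64 ± 0.13. Vasculature genes (median -0.31, adjusted p = 0.00181, and adjusted p = 0.32 with an estimated correlation; the cellulose synthase IRX3 -0.39 ± 0.11) and Aux/IAA genes (median -0.19, adjusted p = 0.0337, and adjusted p = 0.304 with an estimated correlation; IAA28 -0.42 ± 0.15) were lower too. Photosynthesis genes were higher by 0.98, or 1.97-fold (13 of 13 positive, adjusted p = 7.08e-06, and adjusted p = 0.364 with an estimated correlation; LHCA3 0.83 ± 0.26), as was the shoot identity score, 0.64, 1.94 and 1.08 in SHY2-GR mocks 1, 2 and 3 against 0.273, -0.269 and -2.246 in the GFP mocks. Mitosis genes were higher by 0.25 (13 of 13 positive, adjusted p = 0.000273, and adjusted p = 0.32 with an estimated correlation; CDC20.1 0.46 ± 0.13). ARR6 passed the test over all genes without SHY2-GR mock 2 (adjusted p = 0.0333). The Aux/IAA call ended without SHY2-GR mock 1 (adjusted p = 0.132) and without GFP mock 1 (0.0561).

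Of 21552 genes, 4 were called between the mocks, all higher in the SHY2-GR line (3557 at an unadjusted p under 0.05; lowest adjusted p = 0.000119). Leaving out each mock in turn gave 3 to 7 calls, 7 without SHY2-GR mock 2, and leaving out the GFP libraries numbered 1 gave 2230. AT2G44760 (chromosome 2, 18452851 to 18454930) was at 14.3 ± 1.7 against 3.57 ± 0.14 CPM (n = 3 each; log2 fold change 2.00 ± 0.16, adjusted p = 0.000119). The other 3 genes overlap on chromosome 1. The long non-coding RNA AT1G07887 (19963067 to 19964105) was at 28.6 ± 4.6 CPM in SHY2-GR mock and at 0 counts in each GFP mock, at least 204-fold higher. MRD1 (AT1G53480, 19963047 to 19964712) was at 11.0 ± 3.2 CPM against 0 counts, at least 78-fold higher, both against a floor of 3 counts per library. HEI10 (AT1G53490, 19963267 to 19966952), a RING protein of meiotic crossover formation, was at 10.7 ± 1.7 against 4.59 ± 0.43 CPM (1.23 ± 0.15, adjusted p = 0.00729). HEI10 was not called without SHY2-GR mock 3 or GFP mocks 2 or 3 (adjusted p = 0.0554, 0.0555 and 0.075). Over all 7 SHY2-GR libraries AT1G07887 was at 23.91 to 38.24 CPM and MRD1 at 4.06 to 13.41 CPM. In the 9 GFP libraries AT1G07887 was at 0 and MRD1 at 0 to 0.13 CPM.

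**Figure D5:**
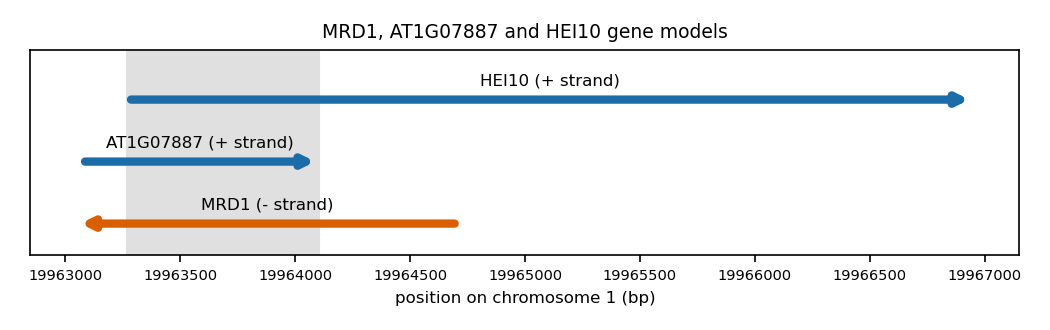
Gene models of MRD1, AT1G07887 and HEI10 along chromosome 1 (positions in bp), drawn to scale as arrows that give the strand, with the region shared by all 3 in grey. The shared region runs from 19963267 to 19964105.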

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

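The difference between lines was among the comparisons fixed before the data were examined, and the tests of explanations in the last 3 paragraphs of this part were chosen after the results had been seen. At 1 µM, 6 gene lists answered dexamethasone differently in the SHY2-GR and the GFP line by camera, and 0 did with an estimated correlation. Root hair growth genes differed by a median of -0.36 (log2, SHY2-GR minus GFP; adjusted p = 3.55e-15, and adjusted p = 0.552 with an estimated correlation). Iron deficiency genes differed by -0.31 (adjusted p = 0.00814, and adjusted p = 0.644 with an estimated correlation), and both calls ended without SHY2-GR 1 µM library 1 (adjusted p = 0.625 and 0.989). Photosynthesis genes differed by 0.58 (adjusted p = 0.00814, and adjusted p = 0.672 with an estimated correlation; LHCB2.1 1.11 ± 0.67), a call lost without SHY2-GR mock 3, SHY2-GR 1 µM library 1, GFP mock 2 or GFP 1 µM libraries 2 or 3 (adjusted p = 0.381, 0.741, 0.121, 0.0726 and 0.0686). Hair and non-hair fate genes differed by -0.18 (adjusted p = 0.0188, and adjusted p = 0.552 with an estimated correlation; CPC, which promotes hair fate, -0.52 ± 0.22), a call lost without SHY2-GR mock 3, SHY2-GR 1 µM libraries 1 or 2, GFP mock 3 or GFP 1 µM library 1 (adjusted p = 0.313, 0.108, 0.117, 0.0684 and 0.0838). Defence genes differed by -0.52 (adjusted p = 0.0418, and adjusted p = 0.552 with an estimated correlation; WRKY33 -1.55 ± 0.62), a call lost without SHY2-GR mock 3, SHY2-GR 1 µM libraries 1 or 2, GFP mocks 1 or 2 or GFP 1 µM libraries 2 or 3 (adjusted p = 0.313, 0.27, 0.164, 0.0787, 0.112, 0.204 and 0.0685). Touch genes differed by -0.60 (adjusted p = 0.0343, and adjusted p = 0.552 with an estimated correlation; TCH4 -0.64 ± 0.30), a call that lasted only without GFP mock 1 and was lost in the other 9, at 0.0581 to 0.248.

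At 0.1 nM, 5 lists differed between lines by camera, and 0 did with an estimated correlation. None of these 5 calls was lost when a library was left out, and with all 3 SHY2-GR mocks the cortex, root cap and niche list was not called (adjusted p = 0.18). Photosynthesis genes differed by a median of 1.71 (adjusted p = 4.61e-08, and adjusted p = 0.466 with an estimated correlation), beside shoot identity scores of 2.41 and 2.02 at 0.1 nM against 0.64 and 1.08 in the labelled SHY2-GR mocks. Cytokinin genes differed by 0.39 (adjusted p = 0.00801, and adjusted p = 0.466 with an estimated correlation). Mitosis genes differed by -0.32 (adjusted p = 0.00129, and adjusted p = 0.466 with an estimated correlation). Hair and non-hair fate genes differed by -0.43 (adjusted p = 0.01, and adjusted p = 0.231 with an estimated correlation). The cortex, root cap and niche list differed by -0.69 (adjusted p = 0.01, and adjusted p = 0.256 with an estimated correlation).

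The mean score of the root hair growth list was 0.66 log2 units lower at 1 µM than in mock in the SHY2-GR line, which may have technical sources. In 1 µM library 1 the fall was larger than any seen with 1 µM dexamethasone in the GFP line. That library lay -1.29 and -1.05 from its mocks, below all 9 pairwise differences of GFP 1 µM minus GFP mock libraries (-0.29 to 0.19). As this is 1 library, no conclusion on an effect of dexamethasone itself is drawn from it. For library 2 such an effect cannot be told apart, because its differences of -0.27 and -0.03 lay within that range. More shoot tissue, which would dilute root hair transcripts, is argued against by the 0.1 nM libraries. Their shoot identity scores of 2.41 and 2.02 came with a root hair median of 0.22 above mocks 1 and 3, a rise not called with all 3 mocks. Their root hair list scores were 0.046 and -0.165, against 0.008 in mock 2 and -1.278 in 1 µM library 1. A property of a single library stays open, because the list had an adjusted p of 0.27 without 1 µM library 1. A response to SHY2 at the higher dose, the explanation that the design names, stays open as a hypothesis that rests on that library.

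How far the 37 calls at 0.1 nM may come from which mocks served as controls stays open: with all 3 mocks 0 were called (lowest adjusted p = 0.203, median size of the log2 fold change 0.74 against 1.03), and against the mock left out alone, whose shoot identity score was 1.94 against 0.64 and 1.08, the median was 0.37 (median SE 0.20), but the genes had been selected on the same 0.1 nM libraries and the labelled mocks. Shoot tissue in the 0.1 nM libraries also stays open as a hypothesis: 10 of the 10 leaf and stomatal lineage genes were higher, by a median of 1.38 (0.51 to 1.82), and the abundant leaf transcripts RBCS1A and LHCB1.3 reached 3560 and 3030 CPM. These 10 genes, none of which is on another list, stood at 0.79 CPM or less in the GFP libraries 2 and 3 of each dose and in GFP mock 3. Whether shoot tissue was the whole cause of the calls cannot be decided with the score as a covariate. With it the median size of their log2 fold changes was 1.02 against 1.03 without it (median SE 0.17 in both), and all 37 remained called. The photosynthesis list, itself a marker of shoot tissue, went only from 1.2 to 0.74, so the covariate removed the shoot signal in part. A response to a low dose of SHY2 stays open beside both.

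Of the 4 genes higher in the SHY2-GR line without dexamethasone, 3 lie at 1 locus and share 839 bp, so that reads of MRD1, AT1G07887 and HEI10 cannot be told apart there: AT1G07887 and HEI10 lie on the same strand, and whether counting used strand, which would part MRD1, is not given in the sources used here. A further rise of the 3 genes with dexamethasone was not seen. At 1 µM the highest log2 fold change of the 3 was 0.07 ± 0.20, for AT1G07887, and the fold change plus 2 SE was at most 0.63. Whether a leak of the fusion raised them without dexamethasone cannot be decided from this, because they were already high in SHY2-GR mock. MRD1 had -0.25 ± 0.44 and HEI10 -0.10 ± 0.18, and at 0.1 nM MRD1 had -1.23 ± 0.46 (adjusted p = 0.211), without overlap between the libraries compared. A difference between the lines at this locus, in their background or through the transgene, was not tested and stays open.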

How the results depend on the processing

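Leaving out the GFP libraries numbered 1, the shoot identity score as a covariate and the fit of SHY2-GR libraries alone were chosen after the data had been seen. For 78 single gene results, 1163 of 1307 alternatives kept the direction and the side of the threshold, 89 lost the call, 45 gained one and 10 reversed. For 45 list results 517 of 724 were kept, 206 lost the call and 1 reversed. Of 145 alternatives for the 8 counts of called genes 100 stayed within 1.5 times, and of 89 for the counts of called lists 57 did. Except where a cause follows from how an alternative was built, the cause was not tested. A left-out library can leave 1 library in a group, which is then assumed to vary like the other groups. Depth limits genes near the floor of 0.14 CPM.

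At 0.1 nM in the SHY2-GR line 37 genes were called. DESeq2 size factors gave 80 (69 higher, 11 lower), no filter on low counts 0, DESeq2's Wald test 990 and the fit of only the compared groups 3503 (2290 higher, 1213 lower). Limma gave 258 (146 higher, 112 lower) on log2(FPKM + 1), which held all 37, and 92 (49 higher, 43 lower) on log2(FPKM + 0.1), which held 33. The threshold of 1 on the log2 fold change, a stricter demand, left 19. With all 3 mocks there were 0, in the SHY2-GR libraries alone 0, without the GFP libraries numbered 1 936, and with the shoot covariate 1163 (732 higher, 431 lower), the last 2 holding all 37. Leaving out each library gave 0 to 20. DESeq2's Wald test called 24 genes at 1 µM in the SHY2-GR line, 14 between doses, 1 and 2 at 1 µM and 0.1 nM in the GFP line, 6 and 505 for the difference between lines at 1 µM and 0.1 nM, and 143 between mocks, against 0, 0, 0, 1, 0, 0 and 4 by edgeR. Leaving out each library gave 0 to 134 genes at 1 µM, 0 to 183 between doses, 0 to 1 at 1 µM in the GFP line, 0 to 7 and 0 to 18 for the differences between lines, and 3 to 7 between mocks. The gene called at 0.1 nM in the GFP line was lost by limma on log2(FPKM + 1) and with only the compared groups (0 genes each). Without a filter 1 gene was called for the difference at 0.1 nM and 8 between mocks. Between mocks limma gave 9 with either pseudocount and the shoot covariate 7. Without the GFP libraries numbered 1 there were 2230 genes (1036 higher, 1194 lower) between mocks and 16 for the difference at 0.1 nM.

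Gene lists lost every call with an estimated correlation, in all 8 comparisons (0 lists). Fry called 3 lists at 0.1 nM in the SHY2-GR line, 2 for the difference at 0.1 nM, 5 between mocks and 0 in the other 5 comparisons. Against 1 list at 1 µM in the SHY2-GR line, all 3 mocks gave 5, the shoot covariate 2 and leaving out a library 1 to 6. All 3 mocks gave 3 in place of 6 at 0.1 nM, and the covariate 3 in place of 6 for the difference at 1 µM. Leaving out a library gave 2 to 7 lists between doses, 2 to 7 at 1 µM and 0 to 7 at 0.1 nM in the GFP line, and 2 to 7 and 5 to 8 for the differences at 1 µM and 0.1 nM.

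Some directions reversed when a library was left out, mostly of values near 0. EXPA7 at 1 µM in the SHY2-GR line had log2 fold changes from -0.96 without 1 µM library 2 to 0.18 without library 1, and between doses, with the same libraries left out, from -0.94 to 0.16. For the difference between lines at 1 µM EXPA7 ran from -1.02 to 0.11, again without libraries 2 and 1. IAA3 between doses ran from -0.27 without 1 µM library 2 to 0.13 without library 1, and had 0.09 without 0.1 nM library 1. The iron deficiency list turned between doses without 1 µM library 1 (adjusted p = 0.89) and had an adjusted p of 3.13e-06 without library 2. At 0.1 nM in the GFP line IAA3 ran from -0.09 without mock 3 to 0.07 without mock 1, with 0.11 without all libraries numbered 1, and EXPA7 from -0.04 without mock 1 to 0.10 without mock 3, with -0.05 without all libraries numbered 1. Between mocks IAA3 ran from -0.01 without GFP mock 3 to 0.16 without GFP mock 1.

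The replicate number was entered as a block. In the paired comparison of GFP 1 µM with mock it called 1 gene and ended the defence call, as given in the report, and changed no other call there. In the other comparisons numbers were not taken to pair libraries, a choice that is uncertain for GFP mock and 0.1 nM. Deviations of same-numbered libraries correlated at 0.55, 0.09 and 0.35 between GFP mock and 0.1 nM, near the 0.58, 0.17 and 0.34 between GFP mock and 1 µM. They correlated at -0.17 and -0.18 between SHY2-GR mock and 0.1 nM and at 0.07 and 0.09 between SHY2-GR mock and 1 µM. Same-numbered libraries of GFP 0.1 nM and GFP 1 µM correlated at 0.64, 0.37 and 0.37, and of the 9 GFP libraries 6 correlated best with their own number. The numbers may thus pair the libraries of all GFP groups, and the block would then be the apt fit at 0.1 nM too. In the comparisons not taken as paired, the block gave 0 genes at 0.1 nM in the SHY2-GR line and 195 between mocks (89 higher, 106 lower). It gave 1 at 0.1 nM in the GFP line, a different gene, AT4G36032 (3.14 ± 0.30, adjusted p = 0.0277), in place of AT5G18475 (adjusted p = 0.152).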

Other observations

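The test of plastid annotation in this part was chosen after the called genes had been seen, and the count of other splits of the libraries before. Many of the genes that rose at 0.1 nM in the SHY2-GR line encode plastid proteins. They included THIC, an enzyme of thiamine synthesis (log2 fold change 1.16 ± 0.17), the plastid proteases VAR2 (0.87 ± 0.14), DEG1 (0.82 ± 0.14) and CLPR1 (0.68 ± 0.11), ZDS, an enzyme of carotenoid synthesis (0.71 ± 0.12), HCF136, a photosystem assembly factor (1.2 ± 0.20), and HCF109, a plastid peptide chain release factor (0.92 ± 0.16). Of the 24 higher genes with an annotated cellular component, 15 (62.5%) were annotated to the chloroplast, against 1972 of 15876 tested genes (12.4%), an odds ratio of 11.8 (Fisher's exact test, two-sided p = 1.07e-08). Of 6 lower genes 0 were (Fisher's exact test, p = 1). In the same libraries the shoot identity score was 2.41 and 2.02 against 0.64 and 1.08 in the labelled mocks, its 10 genes were higher by a median of 1.38, and with all 3 mocks 0 genes were called. With the score as a covariate all 37 called genes remained called, while the photosynthesis list went from 1.2 to 0.74. The higher set may follow plastid content, a hypothesis found and tested on the same data, and no other annotation was tested. Genes that rose outside this set included LSU3, a sulfur-responsive gene (1.72 ± 0.29), the receptor kinase GSO2 (1.14 ± 0.18) and SNC1, an immune receptor (0.96 ± 0.16). Among those that fell were HAT1, a homeobox gene (-0.75 ± 0.10), and PP2CA, a phosphatase of abscisic acid signalling (-0.60 ± 0.10).

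With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For called genes, the real value and the highest of the other splits were 0 and 0 at 1 µM in the GFP line (10 splits gave as many), 1 and 7 at 0.1 nM in the GFP line (2 splits), and 4 and 0 between mocks (1 split). For called lists they were 7 and 5, 6 and 5, and 8 and 7, with 1 split as high in each. The split with 7 genes set GFP mock 1, mock 2 and 0.1 nM library 1, the libraries with the highest shoot identity scores among these 6, against the rest, which points to a structure of the samples. Of the 4 splits that part every pair at 1 µM, the real split called 7 lists and the other 3 called 0, 1 and 5, with 0 genes in each.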
